A study of Homo sapiens with 18 samples.

How the data were processed

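The series measured messenger RNA on 18 one-colour Agilent whole-genome arrays from a reconstructed human epidermis, in 6 groups of 3: control and irradiated tissue at 4, 16 and 24 h. The deposited scanner output of each array came from Agilent Feature Extraction 9.1.3.1. Per the file headers, its processed signal is an intensity, corrected for background and detrended within each array by the authors' software, with no normalization between arrays and no pooling of replicates. The deposited table of all samples held the same intensity values, with a largest difference of 0 from the processed signal. Each array carried 45015 features, of which 1639 were controls. No 2 arrays held identical values.

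Signals were scaled so that every array had the same 75th percentile, of 516.4, and were set to a floor of 10 before log2 was taken, which lies at −5.69 relative to the 75th percentile. Replicate spots, present for 264 probes, were averaged without those that Feature Extraction marked as uneven or as outliers on the array concerned. Where every spot of a probe was marked, as for any marked spot of a single-spot probe, its value was kept. Most marked spots therefore stayed in. The 16 h irradiated arrays had 2833, 1579 and 535 marked spots, against at most 68 on the others. A probe was tested if the software called it well above background on all 3 arrays of at least 1 group, which 29175 probes met. The probe with the highest mean signal stood for each gene. Of 40924 distinct probes, 23617 were named through a RefSeq accession, 2797 through a current symbol and 1121 through an older symbol, and 13389 kept the name in the file. Names came from the RefSeq gene table of assembly GRCh38.p14. The files gave no build for the probes and no reference genome was at hand, so no coordinates are given. Genes that could disclose the sex of a tissue donor were left out of every table. The 22025 genes tested included 14571 with a current symbol. The depth of an array was described by its signal at the 75th percentile and by the share of spots well above background, and the number of arrays limits the precision.

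Groups were taken from the sample titles, except that the dose of the irradiated 4 h group was left open: its titles and treatment tags give 2.5 Gy for replicate 1 and 0.1 Gy for replicates 2 and 3, while the series design and the treatment protocol give 2.5 Gy. A free-text field of the samples names other times, doses and protons. It was used for an alternative grouping only. All 18 arrays were fitted together in limma 3.58.1 (R 4.3.3, with data.table version 1.17.8 and jsonlite 2.0.0), with a mean for each group, a spread shared by all groups (12 residual degrees of freedom) and moderated tests. The comparisons were irradiated against control at each time, their mean over the 3 times, the difference of that effect between times, and control tissue between times. P values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Values are given on the log2 scale as irradiated minus control with the standard error of the fit, and n is 3 arrays per group. Where no array of a group was well above background, the fold is given at a bound. That bound was the lowest signal called well above background on each array, or the gene's own signal where that was higher. The lowest such signal lay at −5.69 to −5.196 relative to the 75th percentile, at or near the floor. Folds at a bound therefore depend on the floor and are not minimum changes. List medians with such members at their bound were the same to 2 decimals, except for the immune marker list at 24 h, at 0.12 in place of 0.05. With the bound at or near the floor, this does not test how far undetected members affect the medians.

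The 24 gene lists covered p53 targets, G2 phase and mitosis, DNA replication, double-strand break repair, keratinocyte layers and activation, barrier lipids, cholesterol, cytokines, interferon, oxidative, unfolded protein and heat shock responses, hypoxia, matrix, immediate early genes, apoptosis, ribosomal proteins and markers of melanocytes, fibroblasts, immune and endothelial cells. They were tested with limma's camera at its preset correlation of 0.01, which compares a list with all other genes, and were adjusted over the lists of a time. Camera with an estimated correlation and fry were run beside it. The lists were written from general knowledge of the pathways and not from these samples. The lists, the tests, the threshold, the alternative settings and the rule for named genes were fixed before the data were examined.

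Named genes were, at each time, the 12 highest and 12 lowest changes among genes with an approved symbol that passed the threshold and whose irradiated arrays all lay on one side of all controls, up to 4 members with the smallest p of each list, and 13 fixed markers of the p53 response, the cell cycle and keratinocyte layers. Added to these were the 10 highest and 10 lowest for the mean over times, the 10 with the smallest p for the difference between times, and the 6 highest and 6 lowest in control tissue at 24 h against 4 h. The rule gave 298 distinct genes, of which 3 are not reported singly. They stay in the counts of genes and lists.

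The procedure was tested on simulated data with the group structure of the real series, each gene's spread within each group, and 22025 genes. Noise was drawn independently for every gene and array, with no effect of slide. At 4 h, 16.4%, 49.3% and 68.2% of genes changed by 0.5, 1 and 2 log2 units were recovered and 26 unchanged genes were called. At 24 h the shares were 10.4%, 38.8% and 68.2%, with 68 unchanged genes called. At 16 h they were 28.4%, 61.2% and 80.3%, but 1229 unchanged genes were called, because the shared spread understated that of the noisier 16 h irradiated arrays. A list of 20 genes shifted by 0.5 was called at 4, 16 and 24 h with camera adjusted p of 7.36e-31, 1.7e-10 and 6.69e-27, and 0 other lists were called. Because the simulated genes were uncorrelated, this cannot show how the list test behaves where the genes of a list vary together.

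Alternatives were quantile normalization, scaling to the median, and normexp background correction with an offset of 50 followed by quantile normalization (normexp below). Others were no filter on dim probes, a filter for signal well above background on all 18 arrays, the mean of a gene's probes and the values of the deposited series file. Each time fitted alone, a block for replicate number, array position, array weights and a change of at least 1.5-fold were also used. So were a random effect of slide, the dose labels, the free-text grouping and each array left out in turn. A floor of 1 or 100, a fit without the 16 h irradiated slide, and an intensity trend with a robust spread were added after the data had been seen. Replicate numbers did not pair samples across groups: deviations of same-numbered control and irradiated arrays from their group means correlated across genes by −0.02 to 0.17, and genes are not independent replicates. Other splits of the arrays were counted with 100 random splits where more were possible (seed 1). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.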

Results

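The response of a reconstructed human epidermis to X-rays was measured at 3 times. The tissue, Epi-200, is built from human keratinocytes that form basal, spinous and cornified layers. Messenger RNA of control and irradiated tissue at 4, 16 and 24 h was measured on 18 arrays, 3 for each of 6 groups. Per the series design, the experiments of a time were independent and each array held a single tissue. The series states a dose of 2.5 Gy, but the titles of irradiated replicates 2 and 3 at 4 h say 0.1 Gy, and a free-text field, which contradicts the titles for other groups too, says 0.1 Gy for all 3, so the dose of that group is open. The signal at the 75th percentile was 372 to 768 intensity units, and 59.6% to 69.7% of spots were well above background. Every group occupied a slide of its own, so slide and irradiation cannot be told apart within a time. Control and irradiated slides of a time were scanned on the same day, the 4 h slides on one day and the later ones on another. The 16 h irradiated slide was noisier than the rest: the SD of its negative control spots was 123.9 to 1019, against 3.09 to 53.1 on the other slides, and its arrays correlated across genes by 0.835 to 0.873, against at least 0.979 within every other group (genes are not independent replicates).

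The comparison at 4 h addressed the early response to exposure. Genes of mitosis were much lower in irradiated tissue. PLK1, a kinase of mitotic entry, fell 13.0-fold (log2 difference −3.70 ± 0.19, SE, n = 3 per group; limma adjusted p = 4.01e-07), from a log2 level of 2.15 ± 0.04 (SD) to −1.55 ± 0.13. UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, fell by 3.24 ± 0.21, and HMMR, a spindle protein, fell by 3.12 ± 0.20. CCNB1, which encodes cyclin B1, was 4.58-fold lower (−2.19 ± 0.28, adjusted p = 0.000641). The centromeric histone gene CENPA was 10.6-fold lower at its bound, as none of its irradiated arrays was well above background. Of 31 measured genes of G2 phase and mitosis, 27 fell and 0 rose, or 29 and 0 adjusted over the list alone. The median was −2.31, with 2 members below background, and the camera adjusted p was 4.63e-60 (adjusted p = 0.000508 with an estimated correlation). The list stood at −2.26, −2.31 and −2.28 on the 3 irradiated arrays and between −0.04 and 0.04 on the controls. MKI67, the gene of the Ki-67 antigen, differed by −2.37 ± 0.84 and did not pass (adjusted p = 0.164).

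Targets of p53 were higher at 4 h. GDF15, a secreted stress cytokine, rose 4.07-fold (2.03 ± 0.33, adjusted p = 0.00354), and CDKN1A, which encodes the cell cycle inhibitor p21, rose 1.95-fold (0.96 ± 0.16, adjusted p = 0.00348). CCNG1 rose by 0.57 ± 0.10 and the death receptor gene TNFRSF10B by 0.73 ± 0.14. MDM2, which encodes the ubiquitin ligase of p53, rose by 1.31 ± 0.29 (adjusted p = 0.0223), a call that ended when any of the 6 arrays of that time was left out. Of 30 targets, 11 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.57 and an adjusted p of 3.56e-10 (adjusted p = 0.00279 with an estimated correlation). BTG2 and FDXR, also targets, differed by 0.02 ± 0.14 and 0.26 ± 0.14 and did not pass.

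Other groups moved less at 4 h. Wound keratins and alarmins of activated keratinocytes had 2 of 16 members higher (5 adjusted over the list alone), the growth factor gene AREG by 0.97 ± 0.16 and S100A8 by 0.56 ± 0.11, with an adjusted p of 0.00195 (adjusted p = 0.145 with an estimated correlation). The S100A8 call ended without control replicate 3 or irradiated replicate 1 or 2. Of 30 DNA replication genes 2 fell (3 adjusted over the list alone), RFC4 and TK1, with a median of −0.33 (adjusted p = 2.04e-05, and 0.145 with an estimated correlation). The TK1 call ended without any of the 6 arrays, and the RFC4 call without any but control replicate 2. Of 24 genes of double-strand break repair 2 fell, H2AX by 0.64 ± 0.11 and FANCG by 0.86 ± 0.17 (5 lower and 1 higher adjusted over the list alone), with a median of −0.42 (adjusted p = 0.000175, and 0.175 with an estimated correlation). The FANCG call ended without irradiated replicate 1. Ribosomal protein genes had 0 members past the threshold, a median of 0.15 and an adjusted p of 0.0228, which was 0.674 with an estimated correlation and passed the threshold neither without control replicate 3 nor without irradiated replicate 2. Cytokine and immediate early lists were not called (adjusted p = 0.0748 and 0.193), but 2 of 22 and 3 of 18 members rose (2 and 4 adjusted over the list alone), among them CCL20, a chemokine gene, by 1.73 ± 0.23 and the AP-1 gene FOSL1 by 1.56 ± 0.28. The inducible cyclooxygenase gene PTGS2 rose 4.47-fold (2.16 ± 0.32, adjusted p = 0.00203) and the collagenase gene MMP1 by 1.35 ± 0.15. The AP-1 gene FOSB was 3.48-fold higher at its bound. KRT15, a keratin of basal cells, fell 3.25-fold (−1.70 ± 0.14, adjusted p = 1.17e-05), while KRT5 and KRT14 differed by 0.06 ± 0.12 and 0.23 ± 0.14 and did not pass.

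In all, 829 genes passed at 4 h, 390 higher and 439 lower, of which 108 and 232 changed at least 2-fold. Irradiated and control arrays did not overlap for 39.0% of genes, against 10% by chance. The count fell to 529 without control replicate 1, 464 without control replicate 3 and 454, 402 and 455 without irradiated replicates 1, 2 and 3. It was 2539 when the noisy 16 h irradiated slide was left out of the fit, where G2 and mitosis (29 of 31 fell) and p53 targets (20 of 30 rose) were again called. With the irradiated array titled 2.5 Gy alone, a lone array that was assumed to vary like the other groups, 144 genes passed, and of the genes above CENPA, GDF15, CDKN1A, CCNG1, TNFRSF10B, MDM2, AREG, S100A8, H2AX, FANCG, FOSL1 and PTGS2 no longer passed. By the free-text field the 4 h tissue at 2.5 Gy would be the 16 h controls. Against the 4 h controls, CDKN1A was lower in them by −0.998 and GDF15 higher by 1.60 (adjusted p = 0.000118 and 0.00113), and neither G2 and mitosis (median −0.32, adjusted p = 0.0858) nor p53 targets (0.887) were called. A response to 2.5 Gy at 4 h thus depends on the labels. The 4 h comparison itself does not, as that field also makes its arrays 4 h controls and 4 h irradiated tissue, at 0.1 Gy. The calls also ended with the mean of a gene's probes for MMP1, with a floor of 100 for CENPA and FOSB, with a floor of 1 for FOSB, and with array position as a factor for TNFRSF10B and MDM2.

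**Figure D1:**
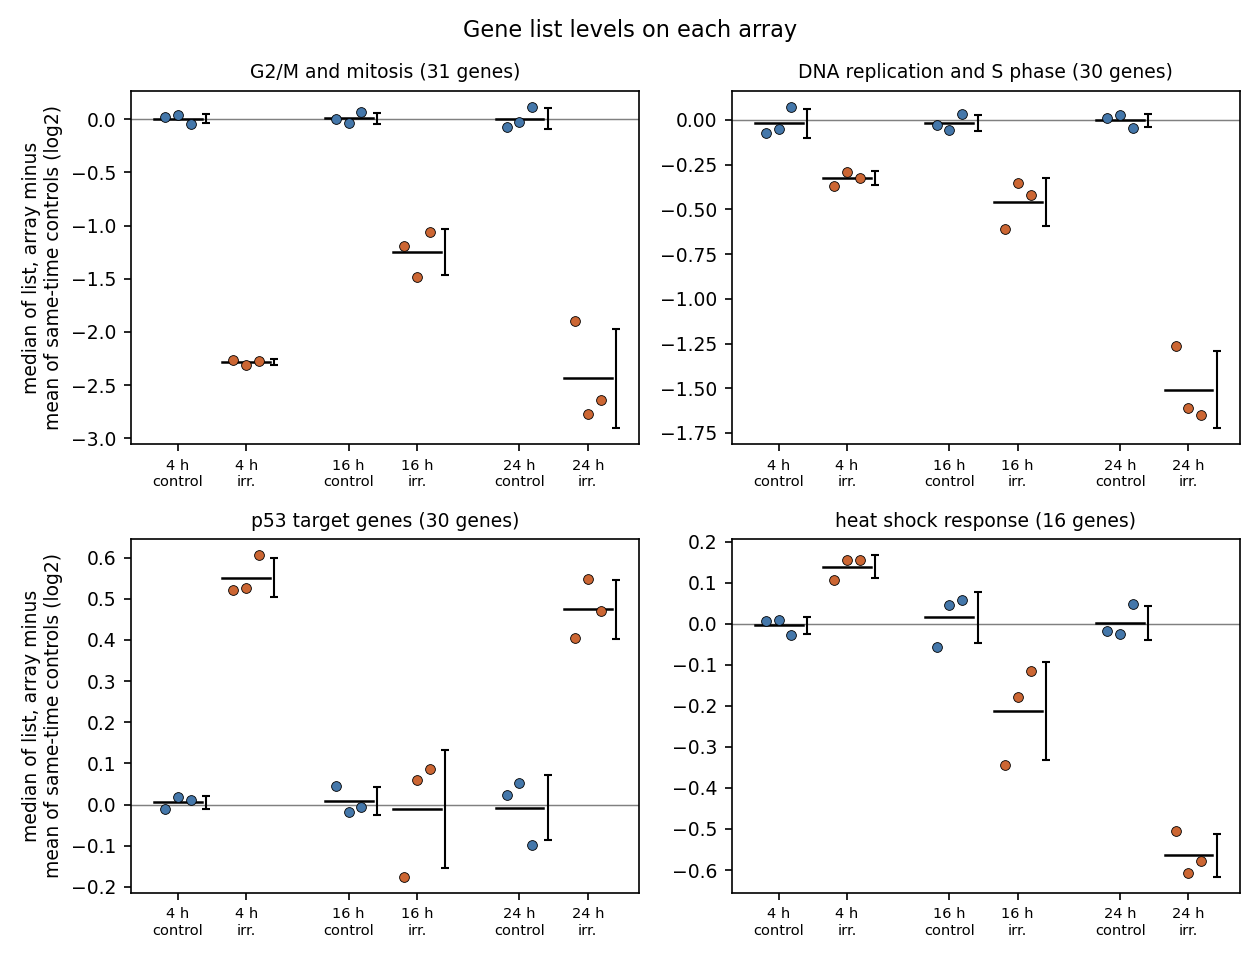
Median log2 level of the members of 4 gene lists on each array, minus the mean of the control arrays of the same time; points are arrays, horizontal lines are group means and bars are 1 SD (n = 3, irr. = irradiated). The 3 irradiated arrays lay below the controls for G2/M and mitosis at every time, at −2.31 to −2.26 at 4 h, and for DNA replication most at 24 h, at −1.65 to −1.26.

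At 16 h, genes of mitosis were again lower in irradiated tissue. CCNB1 fell 2.97-fold (−1.57 ± 0.28, adjusted p = 0.00064) and PLK1 2.44-fold (−1.29 ± 0.19, adjusted p = 0.000113), both well above background on all 6 arrays. CDC25C, a phosphatase that activates CDK1, was 3.16-fold lower at its bound. Of the 31 genes of G2 phase and mitosis, 24 fell and 0 rose (27 and 0 adjusted over the list alone), with a median of −1.29 and an adjusted p of 1.01e-05. This was the single list called, and its adjusted p was 0.914 with an estimated correlation. The median of all genes was −0.30 at that time, against 0.04 at 4 h and 0.03 at 24 h. It varied with scaling, background correction, filter and floor. The values were −0.445 with a floor of 1, −0.42 under median scaling and −0.235 under quantile normalization alone. They were −0.13 under normexp and quantile normalization together, −0.0785 with no filter on dim probes and 0 with a floor of 100. Relative to all genes the G2 and mitosis list was lower by 0.98.

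CDKN1A and BTG2, both targets of p53 that restrain proliferation, rose at 16 h by 0.77 ± 0.16 and 0.79 ± 0.14 (adjusted p = 0.00158 and 0.000603). GDF15 differed by 0.75 ± 0.33 and did not pass (adjusted p = 0.0923). The p53 list went both ways, with 4 of 30 members higher and 6 lower (the same adjusted over the list alone), and was not called. Its median was −0.10, while camera placed it above the other genes. The death receptor gene FAS fell by 1.60 ± 0.23. Of 20 genes of the NRF2 oxidative stress response, 11 fell and 1 rose (11 and 1 adjusted over the list alone), with SRXN1, sulfiredoxin, lower by −1.48 ± 0.17 and GCLM, of glutathione synthesis, by −1.36 ± 0.18. That list was not called against other genes (adjusted p = 0.207). Of 22 cytokine and NF-kB genes 12 fell and 0 rose (the same adjusted over the list alone; adjusted p = 0.29). SOX9, a transcription factor of epidermal progenitors and the hair follicle, fell 18.4-fold (−4.20 ± 0.28, adjusted p = 7.79e-08). KRT1 of the spinous layer and FLG, filaggrin of the cornified layer, rose by 0.59 ± 0.12 and 0.89 ± 0.18, while KRT10 and IVL differed by 0.10 ± 0.13 and −0.09 ± 0.23. The largest rises were in genes such as ADORA1, GRIA2 and MCHR2, 80.8-fold, 51.7-fold and 48.0-fold higher at their bounds. None of these was well above background on a control array. Of the largest falls, CCNA1 was 36.8-fold lower and ZNF256 28.7-fold, both at their bounds. The lowest signal called well above background on the irradiated arrays was −5.667 to −5.376, near the floor, and 32.68% to 34.63% of their spots were below 0. All these folds rest on that noisy slide and are not minimum changes.

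At 16 h, 7941 genes passed, 1494 higher and 6447 lower, and 43.2% of genes had groups that did not overlap (10% by chance). Without irradiated replicate 1, 9211 passed, 2423 of them higher. The noise of the irradiated slide bears on this count: on simulated data 1229 unchanged genes were called at 16 h, and 4189 genes passed when 16 h was fitted alone and 2122 with array weights. Among the 13638 genes well above background on all 18 arrays 4868 passed, a share much like that of all 22025. The free-text field, which makes the 16 h irradiated arrays controls and the 24 h irradiated arrays tissue at 16 h, turned the direction: 9827 genes passed, 7294 higher and 2533 lower, with GDF15 higher by 3.92, the G2 and mitosis list called (median −0.83, adjusted p = 5.92e-07) and p53 targets not (0.0517). Array weights ended the calls of CCNB1, CDKN1A, BTG2, KRT1, FLG and CCNA1, and fitting 16 h alone those of KRT1 and FLG. Normexp and quantile normalization together ended that of KRT1, the mean of probes that of CDKN1A, and a floor of 100 that of CDC25C.

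**Figure D2:**
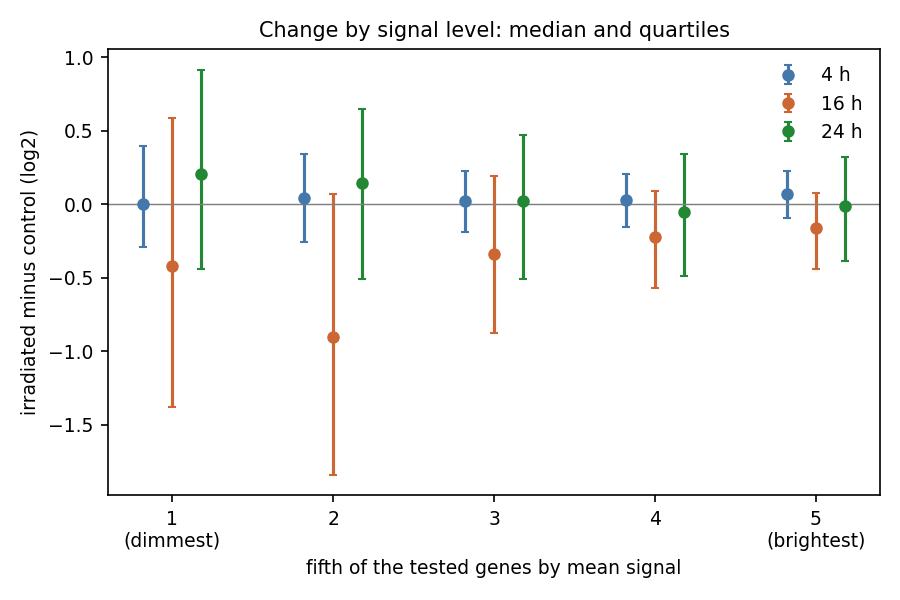
Log2 change of irradiated against control tissue for the tested genes in 5 equal groups by mean signal; points are medians and bars span the quartiles, for 4, 16 and 24 h. At 16 h the medians were below 0 in every group, from −0.90 in the second to −0.16 in the brightest, and at 4 h they were between 0 and 0.07.

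At 24 h, genes of both mitosis and DNA replication were lower in irradiated tissue. BIRC5, which encodes survivin, fell 13.0-fold (−3.70 ± 0.22, adjusted p = 2.12e-07) and the condensin gene NCAPG 15.0-fold (−3.90 ± 0.23, adjusted p = 2.12e-07). MCM2, a subunit of the replicative helicase, fell 6.11-fold (−2.61 ± 0.13, adjusted p = 4.54e-08), and TK1, thymidine kinase, 6.04-fold (−2.60 ± 0.21). RRM2, of ribonucleotide reductase, was 9.98-fold lower at its bound. Of 31 genes of G2 phase and mitosis, 26 fell and 0 rose (27 and 0 adjusted over the list alone), with a median of −2.36 (adjusted p = 2.55e-18, and 0.0374 with an estimated correlation). Of 30 DNA replication genes, 23 fell and 0 rose (the same adjusted over the list alone), with a median of −1.49 (adjusted p = 8.64e-14, and 0.0262 with an estimated correlation). Of 24 genes of double-strand break repair, 12 fell and 0 rose (the same adjusted over the list alone), with H2AX lower by −1.53 ± 0.11, and a median of −0.56 (adjusted p = 1.73e-05, and 0.101 with an estimated correlation).

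GDF15 had the largest rise at 24 h among genes of the naming rule, 21.9-fold (4.45 ± 0.33, adjusted p = 1.13e-06), from 1.63 ± 0.08 to 6.09 ± 0.95 (SD, n = 3). CDKN1A rose 2.01-fold (1.01 ± 0.16, adjusted p = 0.000297), CCNG1 2.15-fold (1.10 ± 0.10) and the decoy receptor gene TNFRSF10C 5.67-fold (2.50 ± 0.40). MDM2 differed by 0.81 ± 0.29, with an adjusted p of 0.0485 that rose above the threshold when any array of that time was left out. Of 30 p53 targets, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.47 (adjusted p = 9.62e-05, and 0.046 with an estimated correlation). The member that fell was FDXR, ferredoxin reductase, by 0.40 ± 0.14, and its call ended without control replicate 1 or 2 or irradiated replicate 3.

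Chaperone genes fell at 24 h: HSPA8, the constitutive HSP70, was 6.95-fold lower (−2.80 ± 0.15, adjusted p = 1.11e-07), and HSP90AA1 and the mitochondrial HSPD1 and HSPE1 were lower by −1.10 ± 0.14, −1.03 ± 0.10 and −1.15 ± 0.15. Of 16 heat shock genes 8 fell and 0 rose (9 and 1 adjusted over the list alone), with a median of −0.56 (adjusted p = 9.62e-05, and 0.0658 with an estimated correlation). Of 22 cytokine and NF-kB genes 12 rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 0.85 (adjusted p = 0.000697, and 0.133 with an estimated correlation). Among them NFKBIA, the NF-kB inhibitor, rose by 1.43 ± 0.26, IL36G by 0.86 ± 0.16, and the adhesion gene ICAM1 was 2.47-fold higher at its bound. Of 18 immediate early genes 8 rose and 0 fell (11 and 0 adjusted over the list alone), including ZFP36, which destabilises cytokine mRNA, by 1.42 ± 0.31 and JUNB by 1.25 ± 0.27 (adjusted p of the list = 0.00104, and 0.256 with an estimated correlation). Of 21 genes of matrix remodelling and TGF-beta 6 rose and 1 fell (the same adjusted over the list alone), with the gelatinase gene MMP9 up by 1.88 ± 0.18 and the urokinase gene PLAU by 1.76 ± 0.27 (adjusted p of the list = 0.0205, and 0.0658 with an estimated correlation).

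Some lipid genes were higher at 24 h. Of 18 barrier lipid genes 6 rose and 0 fell (the same adjusted over the list alone), with FA2H, a fatty acid hydroxylase, up by 1.68 ± 0.16 and SPTLC2, of ceramide synthesis, by 1.59 ± 0.24 (adjusted p of the list = 0.0292, and 0.606 with an estimated correlation). Of 22 cholesterol genes 7 rose and 0 fell (the same adjusted over the list alone), with the sterol enzyme genes SC5D up by 1.56 ± 0.17 and MSMO1 by 1.39 ± 0.17 (adjusted p of the list = 0.0384, and 0.602 with an estimated correlation). Ribosomal protein genes had a median of 0.20, with 4 of 28 higher (2 adjusted over the list alone; adjusted p of the list = 0.0398, and 0.726 with an estimated correlation). The barrier lipid call ended without control replicate 3 or irradiated replicate 2, the cholesterol call without irradiated replicate 2, and the ribosomal call without control replicate 3 or irradiated replicate 2 or 3.

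Keratinocyte layers changed in single genes at 24 h and not as lists. The basal keratin genes KRT14 and KRT5 fell by 0.87 ± 0.14 and 0.64 ± 0.12, and KRT15 fell by 0.96 ± 0.14. The basal list had 2 of 16 members higher and 5 lower (adjusted p of the list = 0.486). KRT10 rose by 0.45 ± 0.13 (adjusted p = 0.0194), a call that ended without control replicate 1 or 2 or irradiated replicate 2 or 3. KRT1 and FLG differed by 0.32 ± 0.12 and 0.40 ± 0.18 and did not pass. Of 15 spinous genes 1 rose and 2 fell, and of 35 cornified envelope genes 0 rose and 5 fell (adjusted p = 0.919 and 0.645). Activated keratinocyte genes went both ways, 3 of 16 up and 3 down, as did 21 interferon-stimulated genes (2 up, 4 down), 20 NRF2 genes (2 up, 3 down), 24 unfolded protein genes (4 up, 5 down), 21 hypoxia and glycolysis genes (4 up, 6 down) and 19 apoptosis genes (6 up, 3 down). Markers of other cell types were measured for 8 melanocyte genes (3 up, 1 down), 6 fibroblast genes (1 up, 1 down), 6 immune genes (1 up, 1 down) and 4 endothelial genes (0 up, 1 down). Adjusted over the list alone, the counts of this paragraph were the same except for 4 cornified genes down, 7 hypoxia genes up, 4 apoptosis and 2 melanocyte genes down and 1 endothelial gene up. The adjusted p of the last 10 of these lists was 0.402 to 0.963. Median, mean and test differed in sign for the melanocyte, endothelial and activated keratinocyte lists, none of them called.

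At 24 h, 6727 genes passed, 2975 higher and 3752 lower, of which 1346 and 1564 changed at least 2-fold, and 59.8% of genes had groups that did not overlap (10% by chance). Without irradiated replicate 3, 4751 passed, 1950 of them higher. The count was 11525 without the noisy 16 h irradiated slide. In that fit the G2 and mitosis, DNA replication and p53 lists had camera adjusted p of 4.05e-16, 1.02e-12 and 0.00037, but 0.116 each with an estimated correlation. Calls ended with the mean of a gene's probes for HSPD1 and MSMO1, with a floor of 100 for ICAM1 and with 24 h fitted alone for ZFP36. The KRT10 call ended with quantile normalization alone, with normexp and quantile normalization together, or with array position. The matrix list was not called without the noisy slide (adjusted p = 0.0567), nor were the cholesterol and ribosomal lists (0.081 for each).

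**Figure D3:**
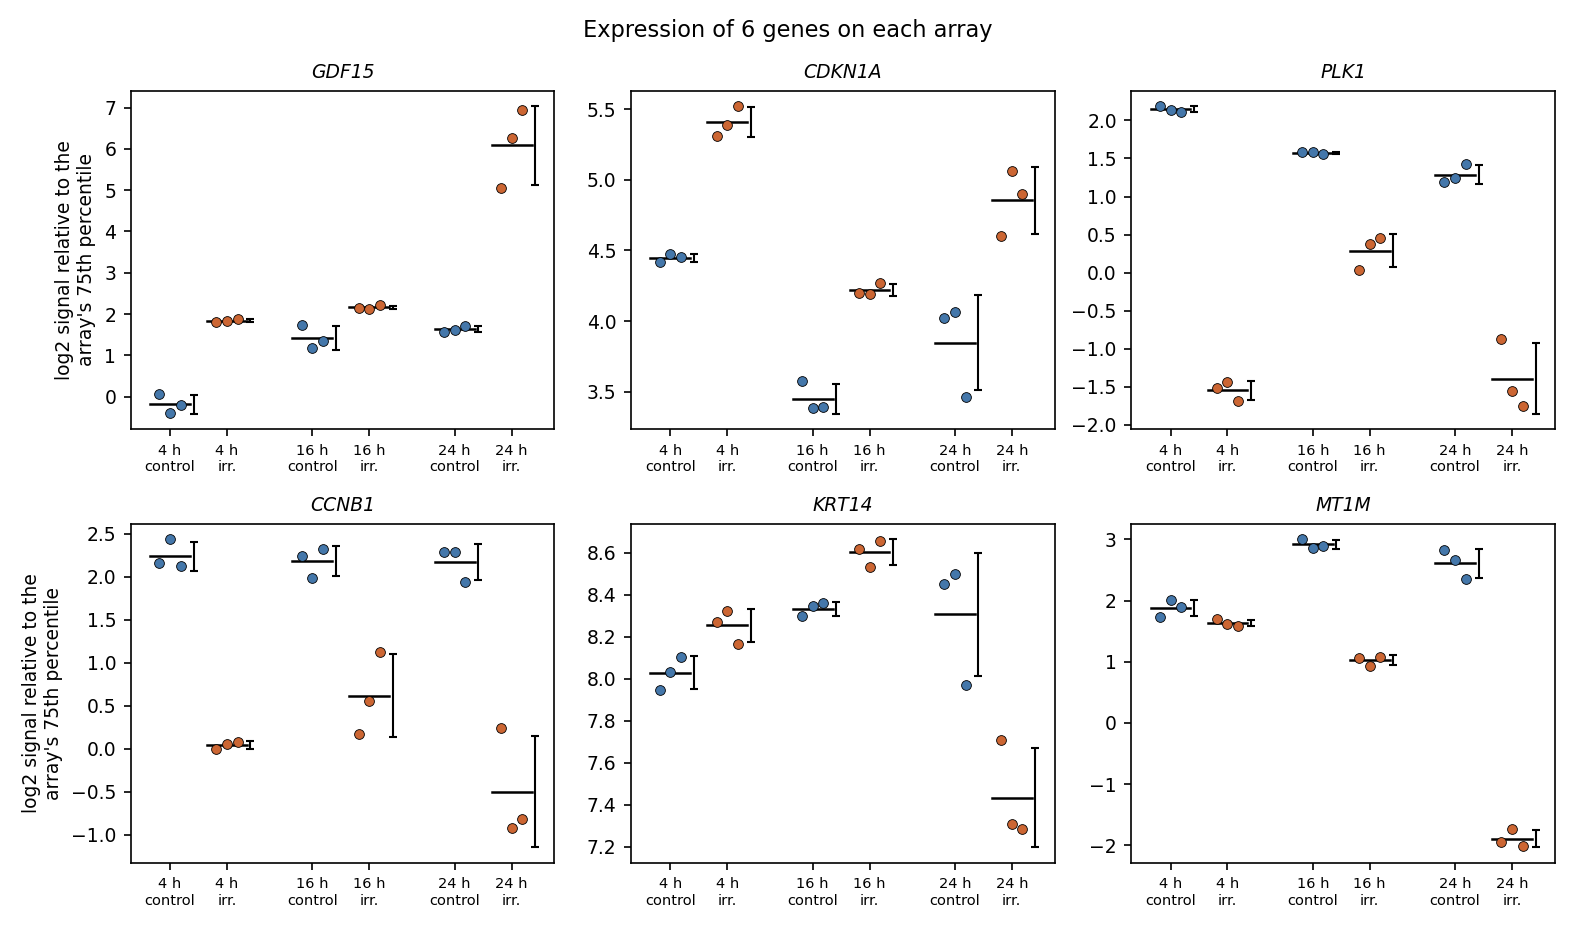
Log2 signal relative to the 75th percentile of the array for 6 genes in each group; points are arrays, horizontal lines are group means and bars are 1 SD (n = 3, irr. = irradiated), and the vertical axes differ between panels. GDF15 at 24 h was 1.63 ± 0.08 in controls and 6.09 ± 0.95 in irradiated tissue, and MT1M was 2.61 ± 0.24 and −1.89 ± 0.14.

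Averaged over the 3 times, TOP2A, the type II topoisomerase of dividing cells, was lower by −3.31 ± 0.30 and CCNA2, cyclin A2, by −2.75 ± 0.19, though both were below the background limit on some irradiated arrays at 16 and 24 h, and GDF15 was higher by 2.41 ± 0.19. Of 31 genes of G2 phase and mitosis 30 fell, and of 30 DNA replication genes 24 fell (31 and 26 adjusted over the list alone), with medians of −2.08 and −0.84 (adjusted p = 1.06e-25 and 2.11e-10, and 0.0109 and 0.0249 with an estimated correlation). Of 30 p53 targets 14 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.31 (adjusted p = 3.57e-08, and 0.0109 with an estimated correlation). Genes of break repair, heat shock, immediate early genes and ribosomal proteins were also called, with adjusted p of 0.000243, 0.0208, 0.0406 and 0.00107, but 0.226, 0.332, 0.633 and 0.633 with an estimated correlation. With slide means as the replicates and the preset correlation, break repair stayed called (camera adjusted p = 0.000102), as did G2 and mitosis, DNA replication and p53 targets. Heat shock, immediate early and ribosomal genes did not (0.166, 0.1 and 0.111). That test takes the genes of a list as nearly independent, so it cannot exclude a slide shift that the members of a list share. In all 6620 genes passed, 1828 higher and 4792 lower, or 8352, 2860 and 5492 without 16 h irradiated replicate 1. Without the noisy 16 h irradiated slide, which leaves the mean of 4 and 24 h, 9352 passed, 4962 higher and 4390 lower. With slide as a random effect 107 genes passed, 7 higher and 100 lower, TOP2A and CCNA2 among them (adjusted p = 0.0149 and 0.00176) but not GDF15 (0.0515).

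The effect of irradiation differed between times for 8904 genes, a count that includes the noisy 16 h irradiated slide. Between 24 and 4 h it differed for 4009, or 8092 with that slide left out of the fit. The fall of DNA replication genes under irradiation was larger at 24 h than at 4 h, with a median difference in effect of −1.24 (camera adjusted p = 8.44e-09, and 0.118 with an estimated correlation). The fall of G2 and mitosis genes was smaller at 16 h than at 4 h by a median of 0.76 over the genes (adjusted p = 1.61e-08, and 0.666 with an estimated correlation). The dose of the irradiated 4 h group is open and every group has its own slide. Time, dose and slide therefore cannot be told apart in comparisons with 4 h, nor time and slide between 16 and 24 h. At all 3 times 98 genes were lower and 11 higher, and CDKN1A was among the latter. Between 4 and 24 h, 108 genes were called higher at both times, against 52.7 if the calls were independent, and 171 lower, against 74.8. In the opposite direction, 103 genes higher at 4 h were lower at 24 h, against 66.4, and 56 lower at 4 h were higher, against 59.3. Between 4 and 16 h, 23 genes were called higher at both times, against 26.5 if independent, and 180 lower, against 129, while 185 genes higher at 4 h were lower at 16 h, against 114, and 43 lower at 4 h were higher, against 29.8. Between 16 and 24 h, 306 were higher at both times, against 202, and 1523 lower, against 1098, while 1026 genes lower at 16 h were higher at 24 h, against 871, and 144 higher at 16 h were lower, against 255. Opposite calls thus exceeded independence in 4 of 6 counts, but not for genes lower at 4 h against 24 h or higher at 16 h against 24 h. The fit shares each gene's spread between times, so calls can coincide beyond independence without a shared effect. An excess over independence therefore does not by itself show a shared response.

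Control tissue also changed between times, in 11535 genes. KRT2, a keratin of the upper spinous layer, was lower at 24 h than at 4 h by −9.49 (n = 3 per group; limma adjusted p = 1.17e-10 over the 3 times), while PSCA and the homeobox gene MSX1 were higher by 5.57 and 5.39. Of 18 barrier lipid genes 12 were lower and 1 higher at 24 h (15 and 1 adjusted over the list alone), with a median of −1.42 (adjusted p = 3.22e-07, and 0.238 with an estimated correlation). Of 35 cornified envelope genes 16 were lower and 8 higher (17 and 8 adjusted over the list alone; adjusted p = 0.0012, and 0.555 with an estimated correlation), and of 21 hypoxia and glycolysis genes 9 were lower and 2 higher (the same adjusted over the list alone; adjusted p = 0.00728, and 0.115 with an estimated correlation). The controls of 16 and 24 h, scanned on the same day, differed in 1937 genes, and those of 4 h differed from them in 10424 and 10262, so that time, scan day and slide cannot be told apart for the change after 4 h.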

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

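The tests of the 16 h slide, of the dose labels and of differences between slides were chosen after the results they address had been seen, and the test of G2 and mitosis genes was divided by time after its first outcome; the counts of other splits were planned. With 3 arrays per group, no test for a single outlying array was made.

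Negative control spots, which no comparison used, had an SD of 1019, 138.9 and 123.9 on the 16 h irradiated arrays, against at most 53.1 on the others. On the same arrays 6447 of the 7941 genes that passed were lower, and the median of all genes was −0.30 (between −0.445 and 0 under other scalings, filters and floors). A wrong scaling factor would give a like shift at every signal level, but the medians of the 5 groups by signal ranged over 0.742. Spike-in transcripts are added to the RNA and do not come from the tissue. At 16 h they were lower by a median of −0.524 (10 spike-ins), against −0.117 at 4 h and −0.0769 at 24 h. Their medians were −0.609 to −0.464 on the 16 h irradiated arrays and −0.212 to 0.346 on the 24 h controls. The brightest, at a mean log2 level of 9.84, differed by −0.00013, and a dim one, at −4.57, rose by 0.226. Those at 4.57, 6.15, 7.90 and 8.56 differed by −0.631, −0.824, −0.576 and −0.377. A shift in background alone would change bright spots least, so it does not account for these falls. Whether noise or background of that slide lowered the genes stays open. An effect of irradiation on most genes cannot be told apart from the slide: all genes lay above the spike-ins by 0.221, but spike-ins and genes were not matched in signal.

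The irradiated arrays at 4 h carry titles with different doses and moved alike. The G2 and mitosis list of the array titled 2.5 Gy differed by 0.031 from the mean of the arrays titled 0.1 Gy, within the range of the controls (0.0784), as a wrong title on some arrays would give. A free-text field gives 0.1 Gy for all 3 arrays and the series design 2.5 Gy, so the labels do not settle which title would be wrong. The p53 list of the array titled 2.5 Gy moved 0.92 times as far as that of the others, a difference of −0.05, outside the range of the controls (0.03). It stood at 0.521 on that array and at 0.527 and 0.606 on those titled 0.1 Gy. The latter differed more from each other, so the difference does not set the 2.5 Gy title apart. The doses as titled stay open, since a single array carries the higher label and a response of both lists that is flat between the doses could give the same values.

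Each group has its own slide, so a difference between slides with no relation to irradiation could shift a list. Between control slides, which also differ in time and scan day, the G2 and mitosis list moved against all genes by at most 0.577, DNA replication by at most 0.20 and p53 targets by at most 0.157. The smaller of the G2 and mitosis shifts at 4 and 24 h was 4.07 times that, the DNA replication shift at 24 h was 7.63 times and the smaller p53 shift at 4 and 24 h was 2.8 times, which argues against slides of the kind seen among the controls as the whole cause. At 16 h the G2 and mitosis ratio was 1.7, and slide and irradiation cannot be told apart for it. These ratios rest on 3 control slides, and the 16 h irradiated slide shows that a slide can differ by more.

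Of the 10 splits of the 6 arrays of a time, the real split called 829 genes at 4 h (402 to 560 with 1 array left out), 7941 at 16 h and 6727 at 24 h, and the highest of the other splits called 4, 27 and 4. It called 6, 1 and 11 lists at 4, 16 and 24 h, and the highest other split 5, 1 and 10, with 2 of 10 splits reaching 1 list at 16 h. In each of the other 5 of these counts 1 of 10 splits, the real one, reached the real value. So few splits cannot give a share under 0.05. For the mean over times the real split called 6620 genes and the highest of 100 splits 5429, for the difference between times 8904 and 7149, and for control tissue between times 11535 and 9125. Chance in the grouping of single arrays is excluded for these 3 counts (1 of 100 splits each, the real one). The splits exchange single arrays, but the 3 arrays of a group share a slide, so they do not exclude a difference between slides, and with slide as a random effect 107 genes were called for the mean over times.

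The effect of irradiation differed between times for 8904 genes, by the test of the difference itself, with the noisy 16 h irradiated slide included. It differed for 4009 between 24 and 4 h, 5615 between 16 and 4 h and 7101 between 24 and 16 h. At 24 h against 4 h the median over a list's genes of the difference in effect was −1.24 for DNA replication, −0.46 for double-strand break repair, 0.53 for barrier lipids, 0.30 for cholesterol and −0.75 for heat shock. At 16 h against 4 h it was 0.76 for G2 and mitosis and 0.10 for the cornified envelope. At 24 h against 16 h it was −0.76 for G2 and mitosis, −1.07 for DNA replication, −0.44 for double-strand break repair, 1.48 for cytokines, −0.37 for heat shock and 1.06 for immediate early genes. None of these 13 differences had an adjusted p under 0.05 with an estimated correlation (0.118 to 0.752). As the 4 h dose is open and each group has its own slide, differences from 4 h may reflect time, dose or slide. Those between 24 and 16 h may reflect time or slide.

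The 10 genes with the smallest p for a difference between times, with their limma adjusted p, were MOGAT2 (6.97e-11), ZNF256 (4.14e-10), TFAP2E (7.18e-10), ZKSCAN4 (2.57e-09), WFDC10A and WDR88 (4.92e-09 each), EGR4 (5.75e-09), MT1M (8.29e-09), TSTD2 (8.55e-09) and MFSD8 (1.78e-08). In each of them except MT1M a group at 16 h had no array well above background.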

How the results depend on the processing

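The floor of 1 or 100, the fit without the 16 h irradiated slide and the intensity trend with a robust spread were chosen after the data had been seen; the other alternatives were planned. For the named genes that passed and are reported singly, 1136 of 1353 results under alternatives at 4 h kept direction and side of the threshold and 217 missed it; at 16 h 2976 of 3400 kept both, 418 missed it and 6 reversed; at 24 h 3200 of 3492, 291 and 1. For called lists the numbers were 139 of 156, 22 of 23 and 219 of 253, with 0 reversed. These totals include the values of the deposited series file, which equal those of the main fit. Its results, 60, 174 and 169 for genes at 4, 16 and 24 h, could not differ. Signal over background limits the 16 h irradiated arrays, where 59.6% to 61.2% of spots were well above background, against at least 63.6% on the other arrays.

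Counts that moved by more than 1.5 times were, with each time fitted alone, 3441 genes at 4 h, 4189 at 16 h and 10380 at 24 h, and 7 lists at 24 h. With array weights they were 7807, 2122 and 13167 genes, 13395 where the irradiation effect differs between times and 18312 where control tissue differs between times. Without the 16 h irradiated slide they were 2539 at 4 h and 11525 at 24 h. At 4 h, 258 genes passed with a block for replicate number, which did not pair the samples (correlations of −0.02 to 0.17), and 432 with array position. At every time controls lay at positions 1, 2 and 3 and irradiated arrays at 2, 3 and 4. Position is therefore partly confounded with irradiation. With the array titled 2.5 Gy alone 144 passed, and 454 with those titled 0.1 Gy, where fewer arrays were compared and a lone array was assumed to vary like the other groups. Leaving out 1 array at 4 h gave 402 to 560, which shows the effect of fewer arrays. The free-text grouping gave 10424 genes at 4 h, because its groups are the 16 h and 4 h controls of the titles. At 16 h it gave 8 lists. Its total there, 9827 genes, moved by less than 1.5 times, but 7294 were higher and 2533 lower, the reverse of the titles. At 16 h, 4868 genes passed among those well above background on all 18 arrays, where fewer genes were tested. For the mean over times 4335 passed with array position and 107 with slide as a random effect. Without the 16 h irradiated slide the total of 9352 moved by less than 1.5 times, but 4962 were higher against 1828 in the main fit (4390 lower). Among the counts by direction alone, 2337 genes were higher at 16 h with no filter, and with a floor of 100, 627 were higher at 4 h and 4049 lower at 16 h. At 4 h 248 were higher without control replicate 2. Without 16 h irradiated replicate 1, 2423 were higher at 16 h and 2860 for the mean over times. At 24 h 1950 were higher without irradiated replicate 3. An estimated correlation gave 2 lists at 4 h, 0 at 16 h and 3 at 24 h. At 16 h fry, which does not compare a list with other genes, gave 16 lists, and no filter, a floor of 1 and a floor of 100 gave 2 each. Except where stated, the cause was not tested.

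Under the mean of a gene's probes the log2 change reversed at 16 h to −1.25 for DST, −0.46 for SPATA18 and 0.81 for RFC3, and to −0.014 for CASP8 at 24 h. With a floor of 100 it reversed to 0.053 for EXO1 and 0.14 for NFKB2 at 16 h, and with normexp and quantile normalization together to 0.050 for DNAJA1 at 16 h. The cause was not tested.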

Other observations

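The metallothionein list and its test, and the comparison between slides, were chosen after the values had been seen, while the list of clock genes and its test were fixed before theirs were.

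Metallothioneins, small proteins that bind zinc and copper, had much lower mRNA in irradiated tissue at 24 h. MT1M fell 22.6-fold (−4.50 ± 0.13, SE, n = 3 per group; limma adjusted p = 1.86e-10), MT1E fell by 4.21 ± 0.17 and MT1X fell by 3.57 ± 0.20. Of 13 measured members 11 fell and 0 rose, with a median of −3.34 (camera p = 5.99e-12, and p = 0.00144 with an estimated correlation), and 11 also fell under quantile, median and normexp scaling. At 16 h 9 fell (camera p = 0.00324, and p = 0.104 with an estimated correlation) and at 4 h 1 fell. The fall was larger at 24 h than at 4 h by a median of −2.78 (p = 2.19e-10, and p = 0.00256 with an estimated correlation). With the 4 h dose open, time and dose cannot be told apart for that difference. In control tissue 11 members were higher and 1 lower at 24 h than at 4 h, with a median of 2.09. The sequences of this family are alike, so that probes may share signal between members, and the list was picked because it moved. The shift at 24 h against all genes was 1.77 times the largest between control slides, so slide and irradiation cannot be told apart for it.

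Some genes of the circadian clock were higher in irradiated tissue at 24 h. BHLHE40, a repressor of clock transcription, rose by 2.51 ± 0.34 and NR1D1, which encodes REV-ERB alpha, by 2.14 ± 0.23, and PER1 rose by 1.23. Of 19 measured genes 7 rose and 0 fell, with a median of 0.92 (camera p = 0.00042, and p = 0.0188 with an estimated correlation). The median at 24 h was 0.92 under quantile normalization and 0.85 under median scaling but 0.34 under normexp, with 7, 7 and 8 members higher. At 4 h CIART alone rose, and 0 members rose under normexp. At 16 h 6 members fell while 1, PER1, rose (3 fell and 2 rose under normexp, and 7 fell and 0 rose under median scaling). The camera p of the list was 0.74 at 4 h and 0.94 at 16 h. The change was larger at 24 h than at 4 h (p = 0.00152, and p = 0.0312 with an estimated correlation). With the 4 h dose open, time and dose cannot be told apart for that difference. One hypothesis was that clock phase differed between collection times in control tissue. There 73.7% of clock genes differed between times, 14 of 19, against 52.4% of all tested genes (2-sided Fisher's exact p = 0.0691), which leaves it open. Times of the controls also differ in slide and scan day. Between control tissue at 24 and 4 h, 7 members were higher and 5 lower, with a median of −0.136. Irradiated and control tissue at 24 h lay on different slides, so slide and irradiation cannot be told apart for the rise. The camera p values of this list were not adjusted over lists.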
